A study of Mus musculus with 2 samples.

How the data were processed

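Total RNA was extracted with Trizol from normal colon of untreated C57BL/6 wild-type mice and from colon adenomas of AOM/DSS-treated mice, and the RNA of 6 individuals was pooled for each of the 2 groups, per the labels. Each pool was sequenced once. The series description names a Proton sequencer while the library protocol names Illumina, so the platform cannot be taken from the labels. The submitters' processing notes name the genome build GRCh37, a human assembly, although the gene symbols are those of mouse, with 29736 of the 35529 found among current mouse RefSeq symbols. The aligner, the counting method and the annotation were not given in the sources used here.

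The authors deposited 1 table of RPKM values, 1 column per pool, with a symbol and a gene type for each of 35529 genes, per the file headers. All symbols were distinct, so summing repeated symbols left nothing to change. Spreadsheet software had turned 25 symbols into dates, and those rows were kept but not named. There were 22388 rows of type mRNA and 8226 of type ncRNA, and 9139 rows were listed at 0 in both pools.

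The read totals behind the RPKM were recovered from single-exon microRNA and small nucleolar RNA genes of known RefSeq length, among which genes with 1 read share the same product of RPKM and length. They were 29548883 for the control pool and 33174626 for the adenoma pool. With these totals, 129 of 183 short genes above 0 in the control pool (70.5%) and 144 of 200 in the adenoma pool (72.0%) came out within 0.01 of a whole read, and the others were fractional. The ratio of the totals, 0.891, was also the most frequent ratio of low values, met by 274 of 3908 genes under 0.3 RPKM. RPKM were turned into approximate reads with the longest GENCODE M21 transcript of each symbol, found for 15492 of the 16517 genes past the filter (93.8%), older symbols being matched through RefSeq synonyms. The authors' own lengths can differ, so reads per gene, and the exact (Clopper-Pearson) binomial 95% intervals of fold changes made from them, are approximate. Where the longest transcript exceeds the authors' length, reads are overstated and the interval is too narrow. In the adenoma pool the estimated reads of genes with a length summed to 33405238, above the recovered total of 33174626. In the control pool they summed to 28741431, below its total. The intervals cover counting error only, not the differences between animals or library preparations. Coordinates are those of GENCODE M21 on GRCm38 and not of the authors' annotation.

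The log2 fold change was log2((adenoma RPKM + 1)/(control RPKM + 1)) for genes with at least 1 RPKM in either pool, and 2-fold on that scale was the threshold. Folds in the text are ratios of RPKM without the pseudocount; no fold is given against a value listed at 0, and a floor of 3 reads per library is used for such genes. With 1 library per group there is no test between conditions and no p-value. Each of 46 gene lists, written down before the values were seen, was described by the median of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn within 20 bins of mean expression. Of the symbols in the lists, 4 were found through RefSeq synonyms and 4 were not found. Genes were named by a rule fixed at the same time: the 12 highest and 12 lowest log2 fold changes among genes with at least 5 RPKM in either pool, leaving out clone, predicted and short RNA names, and for each list the 3 members with the largest absolute log2 fold change, its most abundant member, and where one exists the largest member at least 2-fold in the opposite direction. Not every gene the list part of the rule selects is repeated in each list that holds it, and some are not reported here.

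Other choices listed before the data were seen were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, rescaling to equal sums, scaling by the median ratio, the upper quartile and a trimmed mean of log ratios, thresholds of 1.5-fold and 4-fold, random lists without matching, lists without shared members, and means in place of medians. Added after the data were seen were log2 fold changes adjusted for transcript length, the same adjusted for length and GC content, and mRNA genes alone. The length adjustment subtracted the running median of log2 fold change over 20 bins of transcript length, fitted on mRNA genes, and added back their median.

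The steps were tested on libraries simulated from the real genes and depths, with 200 genes of known fold. Of the genes set 4-fold apart 95.7% passed the 2-fold threshold, of those at 8-fold 100%, of those at exactly 2-fold 10%, and of 14529 unchanged genes 0.110%. The intervals held the true fold for 95.4% of the unchanged genes. These simulated reads held counting error only, with the same transcript lengths as the intervals and no differences between animals or library preparations. The rates therefore check the arithmetic and are not error rates of the genes past 2-fold in the real pools. Among 200 random lists of 20 genes 5.5% fell outside the central 95%, against 55.5% of lists shifted by 0.5 and 98.0% of lists shifted by 1 on the log2 scale. A planted length trend with rho of -0.959 across 12055 genes was reduced to -0.0333. The 20 genes set 4-fold higher had a median log2 fold change of 1.78 after that adjustment, short of the planted value. The planted trend had counting error as its only scatter and was removed with the same lengths. It checks the arithmetic and does not show how well the adjustment works on the real pools, where rho was -0.50. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.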

Results

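RNA was measured in 2 sequencing libraries from C57BL/6 wild-type mice. One was made from normal colon of untreated animals and the other from colon adenomas of animals given azoxymethane (AOM), a colon carcinogen, and dextran sodium sulfate (DSS), which injures the colonic mucosa. The RNA of each library was pooled from 6 individuals, so each group holds 1 library, called the control pool and the adenoma pool here. Values were RPKM, reads scaled to gene length and library size, for 35529 genes, and the read totals behind them came out at 29548883 for the control pool and 33174626 for the adenoma pool. There were 24718 genes above 0 in the control pool and 24984 in the adenoma pool. With no replicates, no difference below has a replicate check, and the 95% intervals beside fold changes cover counting error only. Genes introduced with "in addition" were chosen after their values were seen.

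The comparison of the pools asks how the transcriptome of AOM+DSS adenomas differed from that of normal colon. Many genes of mature absorptive and goblet cells were lower in the adenoma pool. Car4, a membrane carbonic anhydrase, was at 659 RPKM in the control pool and 18.4 in the adenoma pool, 35.7-fold lower (33.3 to 38.4), and Clca3, a secreted goblet cell protein now called Clca1, was 35.5-fold lower (34.5 to 36.5). Many targets of Wnt signalling and antimicrobial genes were higher: the Wnt inhibitor Wif1 stood at 0.347 against 126 RPKM, 362-fold higher (239 to 555), and the matrix protease Mmp7 at 0.116 against 328. Alpha-defensins, which are made by Paneth cells of the small intestine, were listed at 0 in the control pool, while Defa24 reached 237 RPKM, Defa2 177 and Defa3 75.2 in the adenoma pool.

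Of the 12 genes with the greatest positive log2 fold change, metallothionein genes took 2 places. Mt4 was listed at 0 in the control pool, where 3 reads would give 0.255 RPKM, and stood at 501 in the adenoma pool. Mt3 was at 1.07 and 271 RPKM, 254-fold higher (158 to 435). In the GENCODE M21 annotation of GRCm38 these genes lie close together on chromosome 8, Mt4 from 94137197 to 94139031 and Mt3 from 94152607 to 94154146, both on the plus strand. Another close pair, the pancreatic lipase related genes Pnliprp1 (chromosome 19, 58728887 to 58744169) and Pnliprp2 (58759719 to 58777534), was 217-fold (164 to 293) and 167-fold (127 to 225) higher. The others were the calprotectin subunit S100a9, 252-fold higher (136 to 489), the acute phase gene Saa3, 129-fold higher (114 to 145), and Expi, now called Wfdc18, 83.4-fold higher (71.4 to 98.2). Defensin genes are near-identical copies, so their reads cannot be assigned to single members with certainty.

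The 12 genes with the most negative log2 fold change were mostly transporters and secreted proteins of differentiated colon epithelium. Beside Clca3 and Car4 they included the mucus proteins Fcgbp, 27.3-fold lower (26.3 to 28.4), and Zg16, at 4487 RPKM in the control pool and 325 in the adenoma pool, 13.8-fold lower (13.5 to 14.1). The chloride-bicarbonate exchanger Slc26a3 was 22.2-fold lower (20.6 to 23.9), the sulfate transporter Slc26a2 15.3-fold (14.4 to 16.4), the water channel Aqp8 15.5-fold (14.1 to 17.2) and the sugar-phosphate exchanger Slc37a2 18.4-fold (16.5 to 20.6). Tgm3, a transglutaminase, was 17.5-fold lower (17.0 to 18.1). The last 3 were the cytochrome P450 genes Cyp2d12 and Cyp2c55, 48.0-fold (34.9 to 70.2) and 12.4-fold (10.9 to 14.3) lower, and the selenium-binding protein Selenbp1, 9.17-fold lower (8.93 to 9.42). Cyp2d12 and Selenbp1 have close paralogs and are uncertain for the same reason as the defensins.

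**Figure D1:**
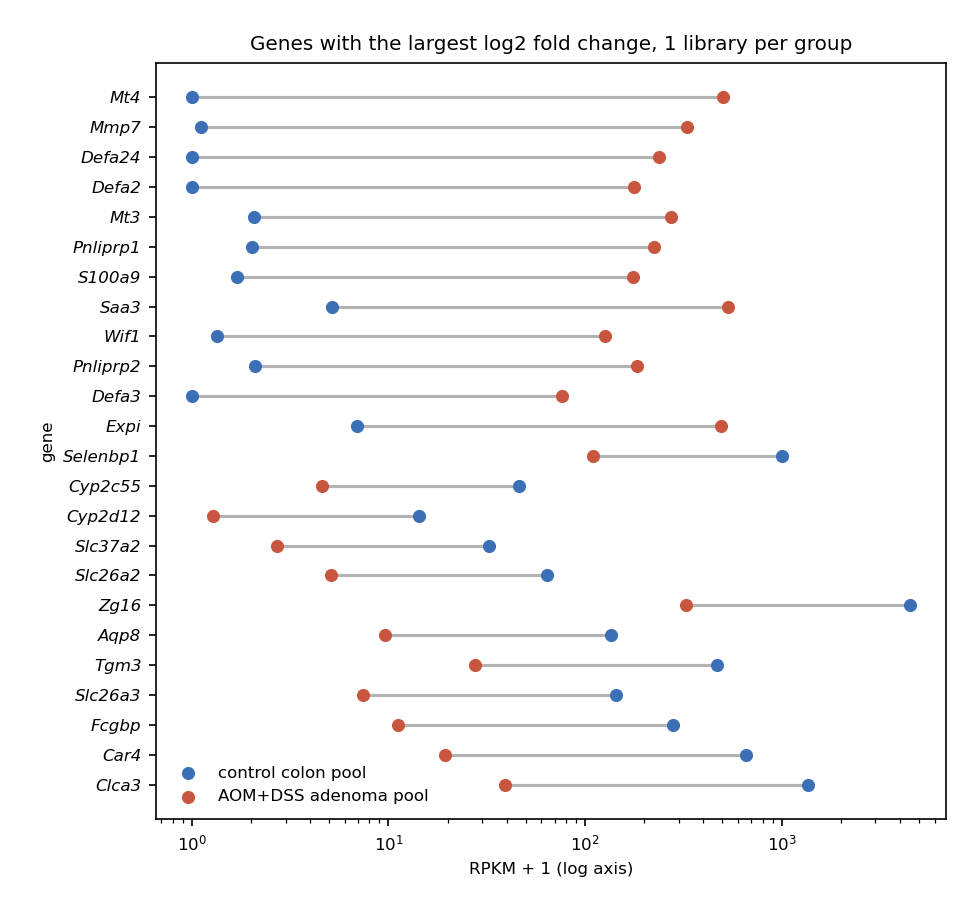
RPKM plus 1 (log axis) of the 24 genes with the largest log2 fold changes, 12 in each direction, in the control colon pool (blue) and the AOM+DSS adenoma pool (red), with 1 library per group and a line joining the values of each gene. Mt4, Defa24, Defa2 and Defa3 sit at 0 RPKM in the control pool, and Zg16 goes from 4487 RPKM in the control pool to 325 in the adenoma pool.

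Over all genes the log2 fold change was taken as log2((adenoma RPKM + 1)/(control RPKM + 1)), which understates the change of low genes. Among 16517 genes with at least 1 RPKM in either pool, 2316 were at least 2-fold higher and 1809 at least 2-fold lower in the adenoma pool, so that 56.1% of the 4125 genes past 2-fold were higher. This split depended on the scale. The RPKM of the adenoma pool summed to 828667 and those of the control pool to 629215, and with both rescaled to equal sums, which lowers log2 values by 0.40 at high RPKM, 1399 genes were higher and 3738 lower (27.2% higher). Among mRNA genes alone 1346 were higher and 1693 lower (44.3% higher), with a median log2 fold change of -0.17.

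Short transcripts were higher and long transcripts lower in the adenoma pool as a whole. The median log2 fold change of mRNA genes went from 0.79 in the 10% with the shortest transcripts to -0.76 in the 10% with the longest, and Spearman's rho between length and log2 fold change was -0.50 across 12718 genes, which are not independent replicates. The 80 ribosomal protein genes, most of them short, had a median of 1.40 (0.59 after length adjustment), with 65 at least 2-fold higher and 0 lower before that adjustment and 19 higher and 1 lower after it, a group chosen after its values were seen. Because of this trend, each gene group below is given with its median after the trend over transcript length was subtracted, a step added after the data were seen that keeps the mRNA median of -0.17. After it, 880 genes were at least 2-fold higher and 1745 lower (33.5% higher) among the 15492 with a length. Among genes named below with small differences, S100a6, Cox4i1, Etfb, Id1, Igkc, B2m, Alox5ap, Sdhb and Tagln were slightly higher before this step and lower after it, such as S100a6 at 0.55 and -0.38 and B2m at 0.21 and -0.71; B2m and Tagln were also lower at equal sums.

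**Figure D2:**
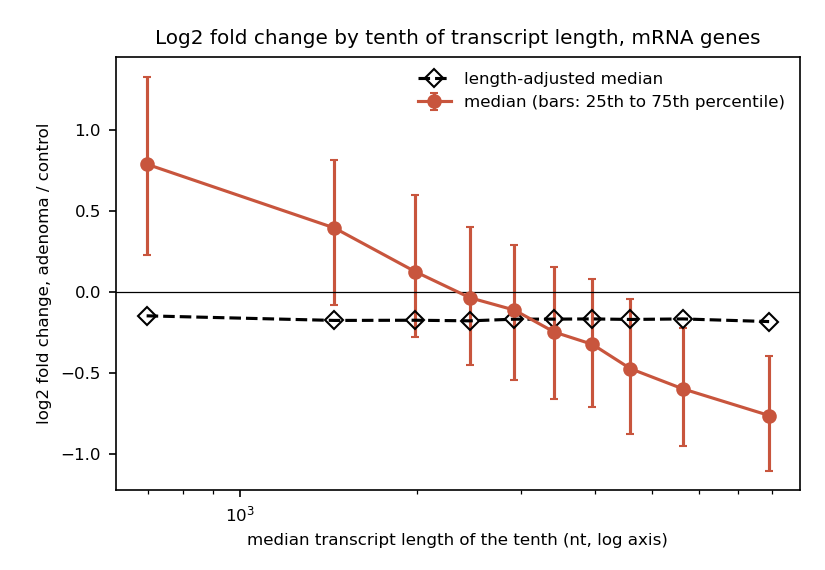
Median log2 fold change between the adenoma and control pools (vertical axis) for mRNA genes in 10 groups of equal size by transcript length in nucleotides (log axis), with bars from the 25th to the 75th percentile of genes, before (circles) and after (diamonds) length adjustment. The unadjusted medians go from 0.79 in the shortest group to -0.76 in the longest.

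Gene lists fixed before the data were examined were described by their median log2 fold change and by its percentile among 10000 random lists of the same size and expression, as a description of these libraries. A list was said to stand apart when it fell outside the central 95% of the random lists. About 2.3 of 46 lists of unrelated genes would do so. There were 28 lists that stood apart, 11 with positive and 17 with negative medians, and 21 of the 28 also stood apart after length adjustment. Lists share members, so these counts are not independent. The genes of a list can also move together with any difference between animals, cell mix or library preparations. The figure of 2.3 therefore does not give the number of lists such differences would set apart, which could not be estimated without replicates. The random lists were not matched on transcript length.

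Wnt/beta-catenin target genes were higher in the adenoma pool as a list. Of 28 measured members, 17 were at least 2-fold higher and 0 lower, and the median of 1.21 (1.43 length-adjusted) lay above all 10000 random lists. Mmp7 and Wif1 led the list, followed by Notum, a secreted Wnt deacylase, at 0.184 against 82.2 RPKM, 446-fold higher (256 to 867). In addition, the feedback inhibitors Nkd1 (3.15 against 83.5 RPKM) and Axin2 (6.21 against 14.4) were higher, and the ligand gene Wnt10a was listed at 0 in the control pool and at 16.8 in the adenoma pool. In addition, 3 well known members were slightly lower, with Myc at 9.96 against 7.40 RPKM, Ccnd1 at 33.0 against 29.4 and Sox9 at 11.1 against 6.59. Cdx1, at 190 against 103 RPKM, was the 1 member at least 2-fold lower after length adjustment, against 17 higher.

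Crypt-base stem cell markers went both ways. Lgr5, a Wnt-dependent stem cell receptor, was 4.71-fold higher (3.91 to 5.75), while Rgmb was 5.18-fold lower (4.65 to 5.81) and Lrig1, an inhibitor of ErbB receptors, 3.14-fold lower (2.97 to 3.33); the most abundant member, Hopx, was 2.03-fold higher (1.90 to 2.16). Of 16 members 3 were at least 2-fold higher and 2 lower, and the median of 0.23, which becomes -0.12 with libraries rescaled to equal sums, lay at percentile 85.5. The length-adjusted median of 0.36 lay at percentile 99.7. Regenerative or foetal-type epithelial genes stood apart, with 9 of 19 at least 2-fold higher, 2 lower and a median of 0.81 (0.46 length-adjusted). Among them the secreted phosphoprotein Spp1 was 51.5-fold higher (31.8 to 88.1) and Ly6d 7.55-fold higher (6.73 to 8.50). The most abundant was the calcium-binding protein S100a6 at 2470 against 3626 RPKM, and Ctgf went the other way, at 51.2 against 21.7 RPKM.

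Genes of proliferation differed little before length was taken into account. Of 40 cell cycle genes 5 were at least 2-fold higher and 0 lower, among them the spindle checkpoint gene Mad2l1, 3.25-fold higher (3.08 to 3.43), Cdca8, 2.48-fold higher (2.30 to 2.66), and the mitotic kinase Cdk1, 2.39-fold higher (2.25 to 2.54), with the replication clamp Pcna the most abundant at 51.3 against 84.8 RPKM. Their median was 0.08, which turns to -0.24 with libraries rescaled to equal sums, at percentile 81.5 of the random lists; after length adjustment it was 0.22, above the central 95% of the random lists. Of 26 ribosome biogenesis and MYC target genes 1 was at least 2-fold higher, Mrto4, with a log2 value of 1.38, and 2 were lower, Utp20 at 3.21-fold (2.98 to 3.46) and Cad at 2.48-fold (2.28 to 2.70). Nucleophosmin, Npm1, was the most abundant at 72.7 against 144 RPKM. The list's median was 0.14, or -0.25 with libraries rescaled to equal sums, at percentile 73.3, and 0.22 at percentile 99.5 after length adjustment.

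Absorptive colonocyte genes were lower together. Of 35 measured members 24 were at least 2-fold lower and 1 higher, and the median of -1.59 (-1.91 length-adjusted) lay below all 10000 random lists. Car4, Slc26a3 and Aqp8 showed the largest differences, and the most abundant member, 2210415F13Rik, now called Lypd8, was at 8210 against 4738 RPKM, 1.73-fold lower (1.72 to 1.74). Electrolyte and water transport genes, which share members with this list, had 18 of 25 at least 2-fold lower, 0 higher and a median of -1.75 (-1.62 length-adjusted), with the cytosolic carbonic anhydrase Car2 at 816 against 128 RPKM, 6.36-fold lower (6.21 to 6.52). Xenobiotic metabolism genes had 20 of 32 at least 2-fold lower, 2 higher and a median of -1.32 (-1.78 length-adjusted). The drug efflux pump Abcb1a was 10.5-fold lower (9.70 to 11.3) and Cyp4f14 6.59-fold lower (5.88 to 7.41), the abundant glutathione transferase Gstp1 was at 336 against 221 RPKM, and the efflux pump Abcc2 was 11.2-fold higher (8.67 to 14.7). The lists of transport and xenobiotic genes also lay below all 10000 random lists.

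Goblet and enteroendocrine cell genes were lower as well. Of 22 goblet cell genes 14 were at least 2-fold lower and 1 higher, and the median of -1.51 (-1.86 length-adjusted) lay below all 10000 random lists. Clca3, described above, was not counted in this list, because its entry was matched first to a separate row named Clca1. After Fcgbp and Zg16 came the transcription factor Creb3l1, 5.39-fold lower (5.11 to 5.68). In addition, the main secreted mucin Muc2 was at 222 against 64.1 RPKM and Atoh1, the secretory lineage factor, at 18.6 against 3.76. Spink4 went the other way, at 1179 against 3289 RPKM, 2.79-fold higher (2.74 to 2.84), with a length-adjusted log2 value of 0.44. Enteroendocrine cell genes had 7 of 14 at least 2-fold lower, 2 higher and a median of -0.99 (-1.50 length-adjusted), at percentile 0.0150. The chromogranins Chgb and Chga were 7.30-fold (6.70 to 7.96) and 5.76-fold (5.17 to 6.43) lower, the abundant peptide hormone Insl5 was at 170 against 113 RPKM, and neurotensin, Nts, was at 0.115 against 2.71 RPKM. Tuft cell genes, with 6 measured, had a median of 0.09 (-0.20 with libraries rescaled to equal sums, -0.26 length-adjusted) at percentile 74.8. Their most abundant member, the actin-binding gene Avil, was 11.5-fold higher (9.78 to 13.7), while Ptgs1 was at 8.53 against 5.78 RPKM and Alox5ap at 5.49 against 7.62.

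Antimicrobial and Paneth-type genes had the highest median of the lists, 4.21 (3.28 length-adjusted), above all 10000 random lists, with 15 of 23 at least 2-fold higher and 4 lower. In addition to Mmp7, Defa24 and S100a9, lysozyme 1 (Lyz1, 37.8 against 337 RPKM), Reg3g (0.394 against 51.1), lipocalin 2 (Lcn2, 4.92 against 163) and Itln1 (3.15 against 118) were higher. Members of the list also moved against it. The most abundant, the acute phase gene Saa1, was 2.43-fold lower (2.41 to 2.46), and the immunoglobulin transporter Pigr was at 1304 against 322 RPKM, 4.05-fold lower (4.01 to 4.10). In addition the goblet cell products Ang4 (174 against 59.9 RPKM) and Retnlb (45.7 against 13.0) were lower.

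**Figure D3:**
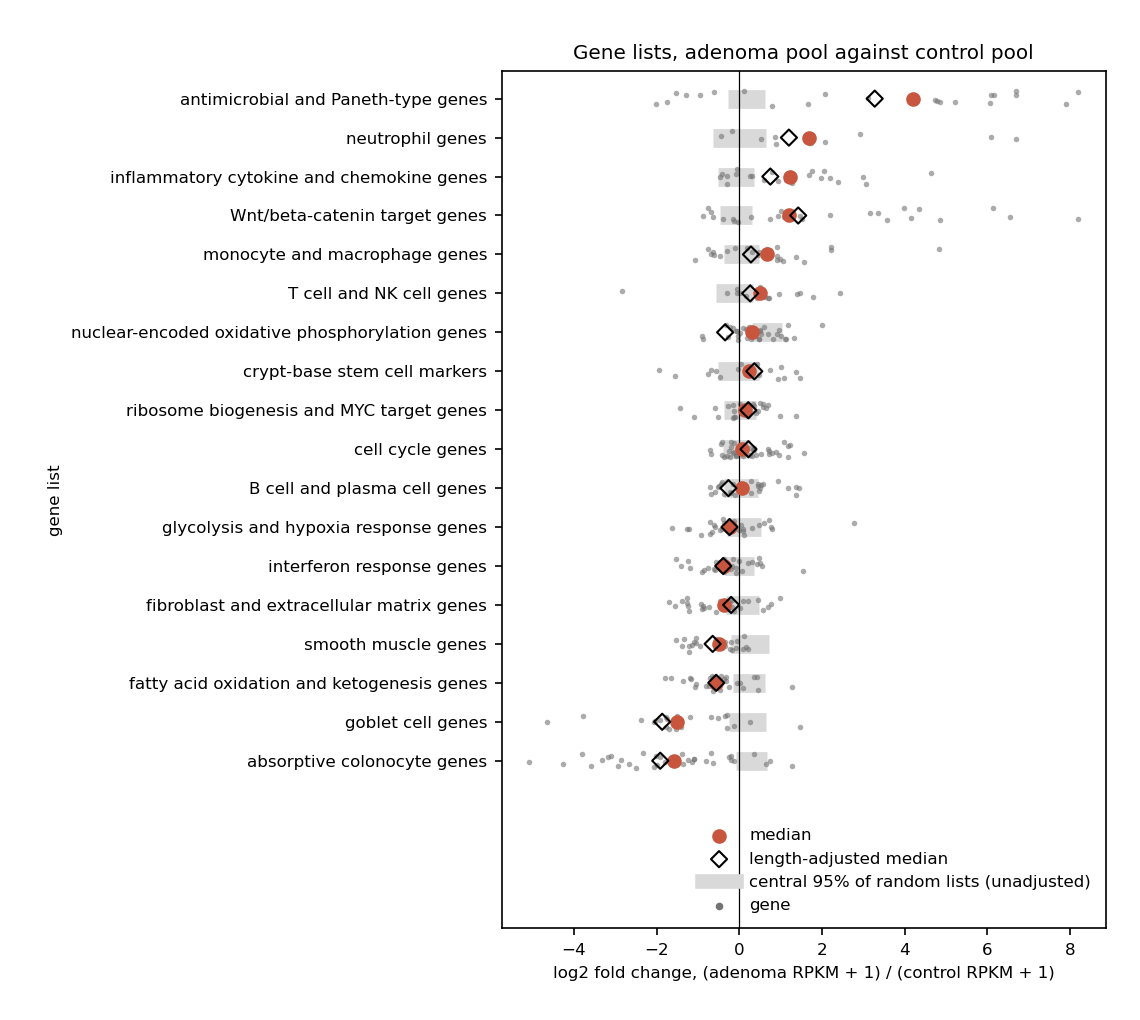
Log2 fold change between the adenoma and control pools (horizontal axis) of the measured genes of each primary list (grey points, jittered vertically), with the list median (red circle), the length-adjusted median (open diamond) and the central 95% of random lists before adjustment (grey bar). Antimicrobial and Paneth-type genes have the highest median, 4.21, and absorptive colonocyte genes the lowest, -1.59.

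Genes of innate immune cells and inflammation were higher. Of 11 neutrophil genes 6 were at least 2-fold higher and 0 lower, with a median of 1.68 (1.20 length-adjusted) above all 10000 random lists. The calprotectin subunit S100a8 was 155-fold higher (89.9 to 323) and Retnlg 22.5-fold (10.9 to 51.5), while the most abundant member, Ly6g, was at 113 against 83.2 RPKM. Without members shared with other lists the neutrophil median was 0.87 at percentile 97.4, within the central 95%. Inflammatory cytokine and chemokine genes had 14 of 25 at least 2-fold higher, 0 lower and a median of 1.23 (0.75 length-adjusted), again above all 10000 random lists. The neutrophil-attracting chemokines Cxcl5, Cxcl1 and Cxcl2 were 51.3-fold (38.4 to 68.6), 16.7-fold (12.5 to 22.8) and 12.7-fold (10.2 to 15.9) higher, and the abundant Ccl8 was 3.47-fold higher (3.09 to 3.89). In addition, Il1b was at 3.90 against 21.4 RPKM and Tnf at 0.962 against 7.09. Mast cell genes had 6 of 9 at least 2-fold higher and a median of 2.19 (1.54 length-adjusted), above all 10000 random lists, with the proteases Mcpt2, 30.7-fold (22.6 to 42.2), Mcpt1, 18.8-fold (14.4 to 24.8), and Tpsb2, 77.2-fold (26.5 to 253), while Kit, a receptor not limited to mast cells, was 6.09-fold lower (5.22 to 7.11). Mcpt1 and Mcpt2 are close paralogs.

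Macrophage and lymphocyte genes differed less. Of 25 monocyte and macrophage genes 6 were at least 2-fold higher and 1 lower, with a median of 0.67 (0.28 length-adjusted) at percentile 99.8. Arginase 1, Arg1, was at 0.275 against 35.4 RPKM, 129-fold higher (73.4 to 249), Trem2 6.33-fold (5.62 to 7.13) and Tyrobp 4.85-fold (4.37 to 5.41) higher, Lyz2 stood at 328 against 621 RPKM, and the scavenger receptor Cd163 was 6.97-fold lower (4.79 to 10.2). T cell and NK cell genes had 4 of 17 at least 2-fold higher, 1 lower and a median of 0.50 (0.26 length-adjusted) at percentile 99.6. Zap70, a kinase of the T cell receptor, was 9.65-fold higher (7.55 to 12.5) and granzyme A, Gzma, 4.57-fold (3.49 to 6.14). The summed RPKM of the 17 members went the other way, from 85.0 in the control pool to 72.4 in the adenoma pool. The list lay within the central 95% without the filter on low values, at a median of 0.0783 and percentile 91.3, and against unmatched random lists, at percentile 97.1. B cell and plasma cell genes had 4 of 27 at least 2-fold higher, 0 lower and a median of 0.06 at percentile 56.8, which turns to -0.32 with libraries rescaled to equal sums and -0.26 after length adjustment. Ighg1 was 2.83-fold higher (2.56 to 3.13), 2010001M09Rik, now called Mzb1, 2.82-fold (2.56 to 3.12) and Iglc1 2.61-fold (2.46 to 2.78), with the kappa chain Igkc at 4655 against 6408 RPKM. Immunoglobulin constant genes share reads with one another. Dendritic cell and MHC class II genes had a median of -0.36 at percentile 4.22, and of -0.68 at percentile 0.615 after length adjustment. In that list the class II transactivator Ciita was 4.77-fold lower (4.09 to 5.61), Cd74 was at 1019 against 588 RPKM, and Batf3 was 2.82-fold higher (2.04 to 4.01). The dendritic cell list also stood apart with a pseudocount of 5, at percentile 0.825, and with a filter at 5 RPKM, at 1.12.

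Interferon response genes were slightly lower. Of 32 members 4 were at least 2-fold lower and 1 higher, and the median of -0.36 lay at percentile 2.19, but the length-adjusted median of -0.39 lay at percentile 6.10, within the central 95%. Also within it were the medians with a pseudocount of 0.1 (percentile 3.71) or 5 (2.61), without the filter (2.73) and against unmatched lists (3.28). Ifih1 and Oasl2, both sensors of viral RNA or its products, were 3.19-fold (2.89 to 3.51) and 3.12-fold (2.89 to 3.38) lower, Usp18 was 3.46-fold higher (2.95 to 4.09), and B2m was at 461 against 533 RPKM. Immune checkpoint genes, with 10 measured, did not stand apart, at a median of 0.04 (-0.25 with libraries rescaled to equal sums, 0.05 length-adjusted) and percentile 65.9. Apart from Arg1, Nt5e was at 32.3 against 19.9 RPKM and Pdcd1 was 5.28-fold higher (2.98 to 10.1). Prostaglandin pathway genes, a list that also holds lipoxygenase genes outside that pathway, had 4 of 19 at least 2-fold higher, 3 lower and a median of -0.42 (-0.30 length-adjusted) at percentile 9.32. The lipoxygenase Alox12 was 28.1-fold higher (21.1 to 38.5), Pla2g2a, a polymorphic pseudogene in the GENCODE annotation, 20.1-fold (17.8 to 22.9) and Alox15 8.31-fold (6.39 to 10.9). The mean of the prostaglandin list had the other sign, at 0.17.

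Muscle and stromal genes were lower or unaltered as groups. Smooth muscle genes had 9 of 24 at least 2-fold lower, 0 higher and a median of -0.49 (-0.64 length-adjusted) at percentile 0.0950. The myosin heavy chain Myh11 was 2.92-fold lower (2.86 to 2.98) and Synm 2.85-fold (2.69 to 3.02), whereas Tagln, the most abundant, was at 558 against 597 RPKM. Fibroblast and extracellular matrix genes had 7 of 28 at least 2-fold lower, 0 higher and a median of -0.38 at percentile 1.05, but after length adjustment the median was -0.20 at percentile 42.4, and against unmatched lists the percentile was 3.07, both within the central 95%. Col6a2 was 3.41-fold lower (3.26 to 3.56), Fbln2 3.14-fold (2.83 to 3.50) and Col6a1 3.03-fold (2.89 to 3.17), while Vim was at 175 against 349 RPKM. Endothelial genes had 3 of 24 higher, 3 lower and a median of -0.77 at percentile 0.0350, and of -0.45 at percentile 5.25 after length adjustment; the mean in place of the median, -0.34, lay at percentile 6.41. Kdr, a receptor of vascular endothelial growth factor, was 3.21-fold lower (2.79 to 3.70), and Sox17 and Egfl7 were 5.92-fold (4.48 to 7.93) and 2.55-fold (2.30 to 2.83) higher, with Plvap at 41.9 against 20.6 RPKM. Enteric neuron and glia genes had a median of -0.53 at percentile 3.19, and of -0.66 at percentile 0.465 after length adjustment; it also stood apart without the filter, at percentile 0.0550, at equal sums, at 2.42, against unmatched lists, at 1.47, and by its mean, at 0.695. L1cam was 5.09-fold (4.68 to 5.55) and Snap25 4.80-fold (3.89 to 6.03) lower, Nos1 was at 1.43 against 0.220 RPKM and the abundant Vip was 1.47-fold lower (1.37 to 1.58).

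Matrix protease and plasminogen-system genes went the other way, with 9 of 21 at least 2-fold higher, 1 lower and a median of 0.71 (0.54 length-adjusted), above the central 95% of the random lists. After Mmp7 came stromelysin 2, Mmp10, 77.1-fold higher (51.0 to 124), and the tissue plasminogen activator Plat, with a log2 value of 2.75. Adamts1 was 3.31-fold lower (2.95 to 3.73). In addition, the collagenase Mmp13 was at 0.962 against 7.52 RPKM.

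Fatty acid oxidation and ketogenesis genes had 7 of 29 at least 2-fold lower, 1 higher and a median of -0.56 (-0.56 length-adjusted) at percentile 0.0150. The rate-limiting carnitine palmitoyltransferase Cpt1a was 3.62-fold lower (3.46 to 3.78), the monocarboxylate transporter Slc16a1 3.28-fold (3.14 to 3.43) and the ketone body enzyme Bdh1 2.66-fold (2.53 to 2.78), and the abundant Etfb was at 179 against 243 RPKM. Nuclear-encoded oxidative phosphorylation genes, which are short, had a median of 0.31 that changed sign with the scale, to -0.09 with libraries rescaled to equal sums and to -0.34 after length adjustment. Before adjustment 6 of 36 were at least 2-fold higher and 0 lower, at percentile 2.82 of the matched random lists, and after it the percentile was 0.720. Ndufa4 was 4.01-fold higher (3.91 to 4.11), Ndufa2 2.53-fold (2.43 to 2.64) and Cox7a2 2.28-fold (2.19 to 2.38), with Cox4i1 at 1022 against 1482 RPKM. Tricarboxylic acid cycle genes had 4 of 20 at least 2-fold lower, 0 higher and a median of -0.17 at percentile 0.495, and of -0.38 at percentile 3.61 after length adjustment, and against unmatched lists the unadjusted median lay at percentile 25.9. Pyruvate carboxylase, Pcx, was 3.45-fold lower (3.25 to 3.66), Ogdh 2.81-fold (2.69 to 2.93) and citrate synthase, Cs, 2.41-fold (2.35 to 2.47), while Sdhb was at 209 against 318 RPKM. Glycolysis and hypoxia response genes did not stand apart, with a median of -0.23 (-0.24 length-adjusted) at percentile 5.18, though without shared members the median of -0.36 did, at percentile 1.44. Hk1 was 3.25-fold (3.10 to 3.42) and Vegfa 2.74-fold (2.46 to 3.06) lower, the lactate exporter Slc16a3 was 10.5-fold higher (9.11 to 12.2), and Ldha was at 700 against 638 RPKM.

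Several signalling lists were lower, mostly without standing apart after length adjustment. EGF family ligands and receptors had 4 of 12 at least 2-fold lower, 0 higher and a median of -0.61 at percentile 2.33 (-0.60 at percentile 3.06 length-adjusted, percentile 2.83 at equal sums, 2.64 with upper quartile scaling, 5.34 among mRNA genes and 6.70 without shared members). Lrig3 was 5.21-fold (4.66 to 5.84), the receptor Erbb3 4.17-fold (3.90 to 4.46) and Erbb2 2.90-fold (2.75 to 3.06) lower. Despite its name the list also holds Lrig1, Lrig3 and Errfi1, which are neither ligands nor receptors of this family. Lrig1 and Lrig3 were among the 4 lower members, so the count is not one of ligands and receptors alone. Notch pathway genes had a median of -0.81 at percentile 0.125, and of -0.27 at percentile 42.1 after adjustment; with a filter at 5 RPKM it was -0.0892 at percentile 49.4. The ligands Dll1 and Jag1 were 6.58-fold (5.19 to 8.51) and 4.01-fold (3.24 to 5.05) lower, Maml1 3.03-fold (2.63 to 3.51), and the target Hes1 was at 27.8 against 26.0 RPKM. BMP pathway genes had 5 of 20 higher and 5 lower, with a median of -0.42 (-0.30 length-adjusted) at percentile 5.19. Bmp2 was 5.37-fold lower (4.82 to 6.00), the activin subunit Inhba 9.68-fold higher (7.43 to 12.7), and Id1 was at 136 against 179 RPKM. Epithelial-mesenchymal transition regulators had a median of -0.51 at percentile 2.07, and of -0.28 at percentile 29.4 after adjustment, with percentiles of 3.02 at equal sums, 6.47 among mRNA genes and 5.79 without shared members. This list pools epithelial genes such as Cdh1 with mesenchymal genes such as Vim, so its median gives no direction of such a transition. Itga5 was 3.14-fold (2.92 to 3.38) and Ovol1 3.70-fold (3.15 to 4.36) lower, and Foxc2 was at 0.0621 against 1.55 RPKM. Tight junction and adhesion genes stood apart in both, with 8 of 20 at least 2-fold lower, 1 higher and a median of -0.77 (-0.66 length-adjusted). E-cadherin, Cdh1, was 3.05-fold (2.96 to 3.14) and Cldn2 3.42-fold (3.25 to 3.61) lower, Cldn4 was 17.0-fold higher (15.2 to 18.9), and Epcam was at 752 against 646 RPKM.

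Immediate early and heat shock genes were lower, with 9 of 19 at least 2-fold lower, 1 higher and a median of -0.87 below all 10000 random lists, as was the length-adjusted median of -0.996. The inducible chaperones Hspa1b and Hspa1a, near-identical copies, were at 126 against 17.6 and 126 against 18.2 RPKM, Klf4, a transcription factor of differentiated epithelium, was 4.14-fold lower (3.99 to 4.31) and Fos 2.76-fold (2.68 to 2.85), while Ier3 was 2.37-fold higher (2.20 to 2.55). Unfolded protein response genes had a median of -0.17 (-0.34 length-adjusted) at percentile 2.73, or 1.35 by the mean, with Sel1l 2.49-fold (2.32 to 2.67), Hyou1 2.31-fold (2.20 to 2.43) and Herpud1 1.86-fold (1.78 to 1.94) lower and the abundant Calr at 456 against 260 RPKM. The p53 target genes had a median of -0.31 (-0.44 length-adjusted) within the central 95%, with Bax 2.62-fold higher (2.46 to 2.79), Btg2 2.25-fold lower (2.12 to 2.39), Sesn2 at 3.49 against 1.30 RPKM and the abundant Perp almost level, with a log2 value of -0.01. Posterior HOX and hindgut transcription factor genes had a median of -0.26 (-0.41 length-adjusted) at percentile 19.8. The intestinal factor Cdx2 was 4.05-fold lower (3.69 to 4.46), Hoxd12 was 3.89-fold higher (3.33 to 4.58), and Hoxb13 was at 315 against 262 RPKM.

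Markers of other tissues were read for the makeup of the pools. Haemoglobin and erythroid genes were higher, with 4 of 5 at least 2-fold higher and a median of 1.58, which was 0.59 after length adjustment, with 0 past 2-fold among the 4 members with a length, a set without Hbb-b1; Hbb-b1 was at 43.8 against 146 RPKM Beta-s, now called Hbb-bs, at 26.1 against 94.0 and Hba-a1 at 31.6 against 96.7. Squamous epithelium genes had 4 of 7 at least 2-fold higher, 0 lower and a median of 1.14 (0.89 length-adjusted) at percentile 99.8, with the keratins Krt14, 9.43-fold (7.70 to 11.7), Krt15, 8.96-fold (5.94 to 13.7), and Krt13, 6.51-fold (4.82 to 8.80) higher and Pkp1 at 18.2 against 13.2 RPKM. Small intestinal enterocyte genes had 4 of 7 at least 2-fold lower, 0 higher and a median of -1.45 (-1.09 length-adjusted) below all 10000 random lists, with Slc15a1 9.07-fold lower (7.39 to 11.1), Apob 5.74-fold (5.05 to 6.53), Rbp2 at 17.0 against 5.45 RPKM, and Fabp2 at 37.6 against 32.4 RPKM. Of the pancreatic acinar genes 3 were measured, with a median of -0.14 (-0.91 length-adjusted) at percentile 27.5, which had the other sign without the filter (0.20) and as a mean (1.94); Pnliprp1 was the one higher, Cela1 was at 321 against 291 RPKM and Cela2a at 1.48 against 0.413. Adipocyte genes had a median of -0.51 at percentile 4.62, and of -0.41 at percentile 15.0 after length adjustment, and stood apart with a pseudocount of 5 (percentile 2.03), without the filter (1.84) and by the mean (0.815), with Car3 16.7-fold (10.6 to 27.1), Cidec 8.02-fold (4.61 to 15.3) and the adipsin gene Cfd 4.03-fold (3.11 to 5.27) lower and Fabp4 at 33.9 against 58.1 RPKM.

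Some reference genes, often used for normalisation, did not hold level between the pools, though as a list they lay near the middle of the random lists. Of 20 measured members 4 were at least 2-fold higher and 2 lower, with a median of 0.46 (0.06 with libraries rescaled to equal sums, 0.22 length-adjusted) at percentile 53.6. Rpl13a was 3.95-fold higher (3.88 to 4.03), Rps18 2.85-fold (2.81 to 2.90) and Ppia 2.41-fold (2.37 to 2.45), and Rplp0 was at 1478 against 2936 RPKM. Of these, Rpl13a, Rps18 and Rplp0 are ribosomal protein genes, the group described above with the length trend. After length adjustment 3 members of the reference list were at least 2-fold higher and 1 lower.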

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

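Adjustment for length, adjustment for length and GC content, and mRNA genes alone were chosen after the result was seen; the cause of the changes below was not tested. Genes higher in the adenoma pool numbered 1309 with a pseudocount of 5, 1399 at equal sums, 880 with length, 818 with length and GC adjustment, 1346 among mRNA genes, 4245 at 1.5-fold and 333 at 4-fold. Genes lower numbered 2858 with a pseudocount of 0.1, 654 with 5, 3738 at equal sums, 4067 at 1.5-fold and 179 at 4-fold, and genes apart 1963 with a pseudocount of 5, 2625 and 2594 with the adjustments, 8312 at 1.5-fold and 512 at 4-fold. The wider and narrower thresholds change counts by construction. With length, then length and GC adjustment, medians were 0.36 and 0.27 for stem cell markers, 0.22 and 0.20 for cell cycle genes, 0.22 and 0.20 for ribosome biogenesis and MYC target genes (all stronger), and -0.34 and -0.33 for oxidative phosphorylation genes (reversed). Among primary lists, those weaker were neutrophil genes without shared members (0.87), T cell and NK cell genes without a filter (0.0783) or matching (0.50), and extracellular matrix genes with the adjustments (-0.20, -0.10), among mRNA genes (-0.38) or without matching (-0.38). Interferon response genes were weaker with pseudocounts of 0.1 (-0.38) and 5 (-0.20), no filter (-0.32), the adjustments (-0.39, -0.40), mRNA genes alone (-0.36) and no matching (-0.36). Glycolysis and hypoxia genes without shared members were stronger (-0.36), and the mean of the pancreatic acinar genes, 1.94, was reversed by Pnliprp1 among 3 genes. Of 643 list values under other choices 586 stood apart or not as before (17 of them with a changed sign), 33 were weaker, 21 stronger and 3 reversed. Of 2033 single-gene values 714 moved; 24, from 11 genes, changed sign, none of a gene past 2-fold. No paired analysis was possible because each group is 1 pooled library.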

Other observations

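Circadian clock, metallothionein and zinc transporter genes were grouped after their values were seen. Of 14 clock genes 8 were at least 2-fold lower in the adenoma pool and 0 higher, with a median of -1.14 (-1.04 length-adjusted). Per2, a repressor of the clock, was 15.9-fold lower (13.6 to 18.7), Per3 6.01-fold (4.98 to 7.32), Cry2 4.49-fold (3.88 to 5.23) and Tef 3.88-fold (3.60 to 4.19), while Nr1d1 was at 9.71 against 8.97 RPKM. The hour of tissue collection was not given in the sources used here. Of 8 metallothionein and zinc transporter genes 4 were at least 2-fold higher and 1 lower, with a median of 1.24 (0.75 length-adjusted). Beside Mt4 and Mt3, Mt2 was 3.84-fold higher (3.54 to 4.18), Mt1 was at 93.9 against 139 RPKM (log2 0.56, or -0.23 length-adjusted), and the zinc transporters went both ways, with Slc30a2 at 0.0409 against 30.5, Slc30a1 3.12-fold lower (2.65 to 3.68) and Slc39a4 at 60.4 against 50.1. Genes listed at 0 in the control pool included the developmental regulators T (brachyury), Cited1, at 18.7 RPKM in the adenoma pool, Fgf3 at 5.40 and Ascl4 at 6.20. The kallikrein genes Klk1 and Klk15, marked by hand in the authors' table, had log2 values of -1.42 and 3.09.

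The fall of log2 fold change with transcript length could come from the libraries or the tissue, and the first of its tests was chosen after the result was seen. Without genes of translation, respiration, the proteasome and splicing rho was -0.490, among genes fitting whole reads -0.458, and at the median of 10 groups of GC content -0.524, so none of these explains it alone. Within lists of related genes rho was negative in 38 of 40 (95%), as a length-dependent recovery of RNA or reads in one library would give. A trend across all genes from any other cause would give the same, so this count does not tell causes apart. A biological difference between short and long transcripts was not tested and cannot be separated from library preparation with 1 library per group.

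Absorptive colonocyte and goblet cell genes were lower, which might reflect length, fewer epithelial cells or less differentiated ones. Their length-adjusted medians of -1.911 and -1.864 exclude length as the whole cause. The pan-epithelial genes, among them Krt8 (4237 against 2514 RPKM) and Epcam (752 against 646), were lower too, with a median of -0.37 and of -0.66 after length adjustment (10 of 29 at least 2-fold lower, 2 higher). They lay 1.248 above the median of both lists pooled (0.550 to 1.67 on resampling genes within this 1 pair of libraries). A lower epithelial share may therefore contribute. It is not the whole cause if pan-epithelial genes held level within epithelial cells, which was not tested. That test was chosen after the result was seen and replaced an earlier one, a fixed bound on the pan-epithelial median, whose bound lay inside the resampled range. Loss of differentiation within cells and a change in the mix of epithelial cells remain possible.

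Paneth-type defensin genes such as Defa24 and the lipase genes Pnliprp1 and Pnliprp2 might have come from small intestine or pancreas caught in the adenoma pool. In tests chosen after the result was seen, the highest of 6 enterocyte genes (Apoa1, Apoa4, Apoc3, Fabp1, Sis, Lct) stood at 0.230 RPKM and the highest of 9 acinar genes, among them Cpa1, Pnlip and Cel, at 0.375 RPKM in that pool. Fabp2 and Cela1, present in both pools, were not in those sets. Admixed tissue at levels that would supply Defa24 at 237 RPKM is not supported by these values. Expression by adenoma cells was not tested directly.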
